A study of Mus musculus with 10 samples.

How the data were processed

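RNA was sequenced from brain immune cells of 10 male C57BL/6 mice, 5 injected with an empty adeno-associated virus vector of serotype 1/2 (EV) and 5 with the same vector carrying human α-synuclein with the A53T mutation (A53T). The mice were injected at 10 to 12 weeks of age and the cells were isolated 16 weeks later, at 26 to 28 weeks, from substantia nigra and striatum by collagenase digestion and a Percoll density gradient, per the labels' protocols. No cell sort is named there. Libraries were made from 0.5 ng of total RNA with a stranded total RNA kit for very low input, with 5 and then 15 cycles of PCR, and sequenced as single reads of 75 nt, per the labels' protocols.

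The authors deposited 2 tables over the same 45906 gene rows. The first holds raw read counts per gene, not normalized. The second holds values on a log2 scale, the regularized logarithm (rlog) of the counts, which the authors made to even out the variance of weakly expressed genes. Both carry RefSeq gene names and coordinates and an extra row, aSyn, for the transgene sequence of 456 bases. The submitters' processing notes name cutadapt 2.5, STAR 2.7.2b, featureCounts 1.6.4 and DESeq2 1.24.0 and the builds mm10 and GRCm38.p6, with no role, order or setting for any of them. Whether reads were counted by strand is not given in the sources used here, so reads of overlapping and antisense genes may have been mixed. Chromosome numbers came from a RefSeq gene table of GRCm38.p6, matched by gene identifier with the same start and end.

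Library totals in the count table lay between 12386305 and 21780086 counts. A gene at 0 in a library could still have been present at up to 3 reads, which was 0.137 to 0.238 CPM (counts per 1000000 after scaling) over the 10 libraries. The reads carry no molecular identifiers in the deposited counts, so such floors and the 95% intervals cover counting error only.

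The comparison of A53T with EV was fitted to the raw counts with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F test with robust dispersions, after TMM (trimmed mean of M values) normalization and edgeR's default filter on low counts, which kept 17409 genes. P-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. CPM values are counts divided by the TMM-scaled library size. Standard errors of log2 fold changes were taken from the fold change and its F value. 40 gene lists, 19 of cell type markers and 21 of programmes, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes where at least 3 members passed the filter, which 37 did. Of the others, NK cells had 1 tested member, mast cells and basophils had 2, and the 13 mitochondrially encoded genes had no row in the table. Each list also received a score per library, the mean log2 CPM of its members with a prior count of 2, and scores were compared by a 2-sided exact permutation test over all 252 assignments of the mice, whose smallest possible p is 0.00794. The tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

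The rule named, in each direction, up to 12 genes past the threshold with an average log2 CPM of at least 1, filled up with those of smallest p where fewer passed. It also named markers of the cell preparation, and up to 4 members of smallest p in each list described, of which the first 2 are given for each list that camera called. Predicted and unnamed loci were passed over. 2 genes that the rule named are not reported here.

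The analysis was tested on counts simulated from the means and library sizes of these libraries with 50 genes changed at each of 4 sizes. The changed genes were drawn from those with an average log2 CPM of at least 1. For the comparison of A53T with EV, with 16846 genes tested, the test recovered 8% of genes changed 2-fold, 62% of those changed 4-fold, 92% of those changed 8-fold and 98% of those changed 16-fold, with 7 false calls among 137. The simulated genes varied independently of each other, which real genes in these libraries did not.

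The alternatives were DESeq2 1.42.0, limma-voom with sample weights, limma on the rlog values, other size factors, other filters, other thresholds, the replicate number as a block, covariates for carried-over cells, a surrogate variable from sva 3.50.0, other list tests and scores, and leaving out each library in turn. After the data were seen, 4 more were added, namely leaving out A53T replicates 3 and 4, the microglial minus neuronal score as a covariate, removal of ribosomal RNA rows, and a term for libraries with at least 100 reads of the salivary gland gene Bpifa2. The covariate for carried-over cells was the mean of the neuron, astrocyte, oligodendrocyte and endothelial scores. It and the microglial minus neuronal score hold scores of tested lists, and adjusting a list for its own score takes out its difference by design. The surrogate variable followed the microglial minus neuronal score with r = 0.99. No 2 libraries held the same counts, since the smallest chi-square per degree of freedom between any 2 was 16.5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.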

Results

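The series measured gene expression in the immune cell fraction of substantia nigra and striatum, 16 weeks after an adeno-associated virus delivered either no transgene (EV, 5 mice) or human A53T α-synuclein (5 mice), a mutant form of the protein that aggregates in Parkinson disease. The design asks how brain immune cells differ when neurons are made to express this protein. The EV libraries held 18136892 ± 3614016 counts and the A53T libraries 17314069 ± 2499118 (SD, n = 5 each). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 40.1 ± 7.88% of the counts in EV and 29.9 ± 16.5% in A53T (SD, n = 5 each), with an exact permutation p of 0.246 (2-sided).

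The transgene was read in the A53T libraries at 73.9 ± 53.1 CPM (SD, n = 5) and in the EV libraries at 0.0123 ± 0.0274 CPM (SD, n = 5). A53T replicates 1, 2, 4 and 5 held 1520, 2223, 1397 and 1217 transgene reads. A53T replicate 3 held 10 reads, or 0.456 CPM, which is 142 times below the lowest of the other A53T libraries. A single read was counted over the 5 EV libraries, against 6367 over the A53T libraries, and the ratio of reads over summed TMM-scaled library sizes was 5678 with an exact 95% counting interval of 1019 to 224294. All 5 A53T libraries lay above every EV library (exact permutation p = 0.00794, 2-sided, the smallest this design can give). The edgeR quasi-likelihood test gave aSyn a log2 fold change of 11.92 ± 1.53 (SE) with a Benjamini-Hochberg adjusted p of 0.105, so the transgene did not pass the threshold over all genes. It passed without A53T replicate 3 (edgeR adjusted p = 5.56e-06).

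**Figure D1:**
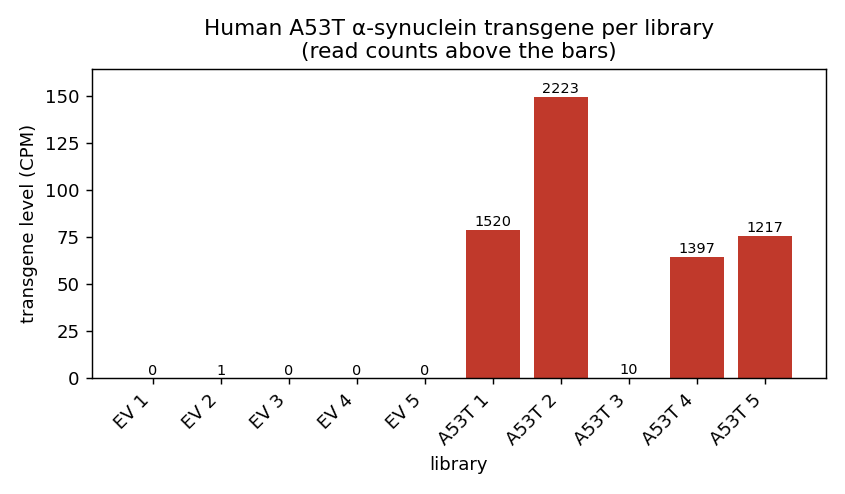
Level of the human A53T α-synuclein transgene in each library, in CPM, with the read count above each bar. 4 A53T libraries hold 1217 to 2223 reads, A53T replicate 3 holds 10, and the EV libraries hold 0 or 1.

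The fraction contained microglia together with RNA of neurons and other glia. P2ry12, a purinergic receptor of resting microglia, was at 122 ± 70.6 CPM in EV and 271 ± 246 CPM in A53T, and the microglial marker Tmem119 at 43.5 ± 33.4 and 106 ± 89.3 CPM (SD, n = 5 each). Snap25, a synaptic vesicle fusion protein of neurons, was at 215 ± 67.2 CPM in EV and 157 ± 110 CPM in A53T, the myelin gene Mbp at 2008 ± 453 and 1783 ± 1036 CPM, the astrocyte water channel Aqp4 at 126 ± 44.0 and 102 ± 56.4 CPM, and the endothelial tight junction gene Cldn5 at 19.4 ± 4.62 and 19.4 ± 7.50 CPM (SD, n = 5 each). Mrc1, a marker of border-associated macrophages, was at 5.14 ± 3.84 CPM in EV and 14.3 ± 12.8 CPM in A53T. The T cell genes Cd3e and Cd8a had 82 and 83 reads over all 10 libraries, too few to be tested, while Cd4 had 1883. The Cd4 reads did not follow the microglial marker P2ry12. Cd4 was lowest in A53T replicate 4 at 2.40 CPM, where P2ry12 was highest at 568 CPM and the neuronal gene Snap25 lowest at 35.3 CPM. It was highest in A53T replicate 2 at 21.0 CPM, where P2ry12 was lowest at 24.7 CPM and Snap25 highest at 304 CPM. The Cd4 reads thus went with neuronal RNA in these libraries and cannot be read as a measure of T cells. Their cell source was not tested. The neutrophil gene S100a8 had 145 reads and the monocyte gene Ly6c2 had 245. None of the tested markers given here passed the threshold in the edgeR quasi-likelihood test, with Benjamini-Hochberg adjusted p-values from 0.957 to 1.00.

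**Figure D2:**
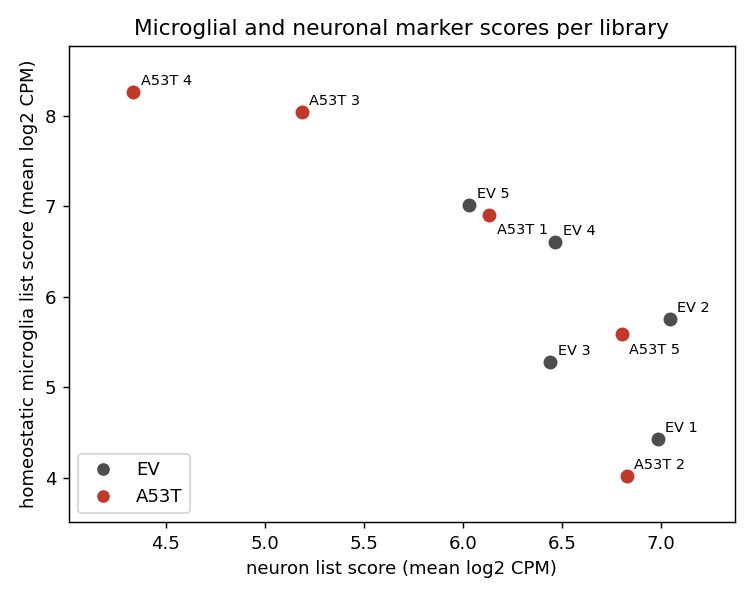
Score of the homeostatic microglia list (vertical axis) against that of the neuron list (horizontal axis), each the mean log2 CPM of the members in a library, for EV (grey) and A53T (red). A53T replicates 3 and 4 have the lowest neuron scores, 5.19 and 4.34, and the highest microglia scores, 8.04 and 8.26.

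Across the 10 libraries the neuron and homeostatic microglia scores went in opposite directions (Pearson r = -0.86, permutation p = 0.00073; Spearman correlation = -0.82, permutation p = 0.00573; adjusted p = 0.00073 and 0.00573 over 5 relations). Without A53T replicates 3 and 4, the libraries farthest from the median neuron score, r was -0.75. With group means removed r was -0.85 (permutation p = 0.009). Both scores are made from shares of the same library total, so a negative r is partly built in. The permutation p-values do not allow for this. The neuron score also rose with the share of mitochondrial ribosomal RNA (r = 0.97, permutation p = 1e-05, the smallest the resampling can give; Spearman correlation = 0.90, permutation p = 0.00075; adjusted p = 1.67e-05 and 0.000937), and r was 0.91 without the same pair of libraries. The score of the cell cycle list followed that of homeostatic microglia (r = 0.921, permutation p = 3.5e-04). At least 100 reads of the salivary gland gene Bpifa2 were found in libraries of 3 EV and 2 A53T mice, too few for a correlation among them or among the rest. Mean homeostatic microglia scores were 5.16 in EV and 5.46 in A53T among these libraries, and 6.81 and 7.29 among the rest. Mean neuron scores were 6.82 and 6.48, and 6.25 and 5.44 among the rest. The gland reads thus overlapped with the microglial to neuronal share, with A53T replicates 1 (score 6.91) and 5 (5.59) going the other way.

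Apart from the transgene, the genes of smallest p with higher levels in A53T included Tpst2, a Golgi enzyme that sulfates tyrosines, at 11.2 ± 1.67 CPM in EV and 24.1 ± 9.49 CPM in A53T (SD, n = 5 each). Ulk3, a kinase of the autophagy-related ULK family, was at 7.55 ± 1.83 and 13.8 ± 0.510 CPM. The β-tubulin gene Tubb6 was at 1.78 ± 1.62 and 8.59 ± 5.77 CPM, and the guanine nucleotide exchange factor gene Arhgef37 at 1.08 ± 0.504 and 3.50 ± 0.698 CPM. Lower in A53T were Abtb2, at 15.0 ± 2.32 CPM in EV and 9.02 ± 0.507 CPM in A53T, and Nptx2, a neuronal pentraxin of excitatory synapses, at 10.9 ± 4.50 and 5.27 ± 1.06 CPM (SD, n = 5 each). None of these passed the threshold.

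The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 17409 genes. At an unadjusted p under 0.05 there were 378 genes, 256 higher and 122 lower in A53T, where 870 would be reached by chance. DESeq2 called 2 genes (1006 at an unadjusted p under 0.05), limma-voom with sample weights called 0 (1210) and limma on the rlog values called 0 (448). The genes called by DESeq2 were aSyn and B430306N03Rik. The log2 fold changes of Tpst2, Ulk3, Arhgef37 and Tubb6 were 1.11 ± 0.27, 0.87 ± 0.22, 1.68 ± 0.44 and 2.26 ± 0.67 (SE), and those of Abtb2 and Nptx2 were -0.73 ± 0.19 and -1.04 ± 0.31 (SE), each with an edgeR adjusted p of 0.957. The other genes named in the higher direction were Marveld1 (1.26 ± 0.34), Pgpep1 (1.00 ± 0.31), Comtd1 (1.87 ± 0.57), Zfp53 (0.90 ± 0.29), Cmtm8 (2.17 ± 0.70), Nxpe3 (0.94 ± 0.30) and Arhgap27 (0.62 ± 0.20), all as log2 fold change ± SE. The log2 fold change of Cmtm8 was 1.29 without A53T replicate 4. In the lower direction they were Zfp930 (-1.41 ± 0.41), Trim17 (-0.85 ± 0.26), Qtrt2 (-0.81 ± 0.25), Unkl (-0.52 ± 0.16), Hmgn3 (-0.67 ± 0.21), Inha (-1.44 ± 0.46), Pdzrn3 (-0.95 ± 0.31), Zc3hav1l (-1.04 ± 0.35), Ube2ql1 (-0.94 ± 0.32) and Xrcc4 (-0.75 ± 0.26). The edgeR adjusted p of each was 0.957. In simulated data of this design 62% of genes changed 4-fold were recovered and 8% of those changed 2-fold. Those genes varied independently and left out weakly expressed genes, so the shares may overstate what could be detected in the real libraries.

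**Figure D3:**
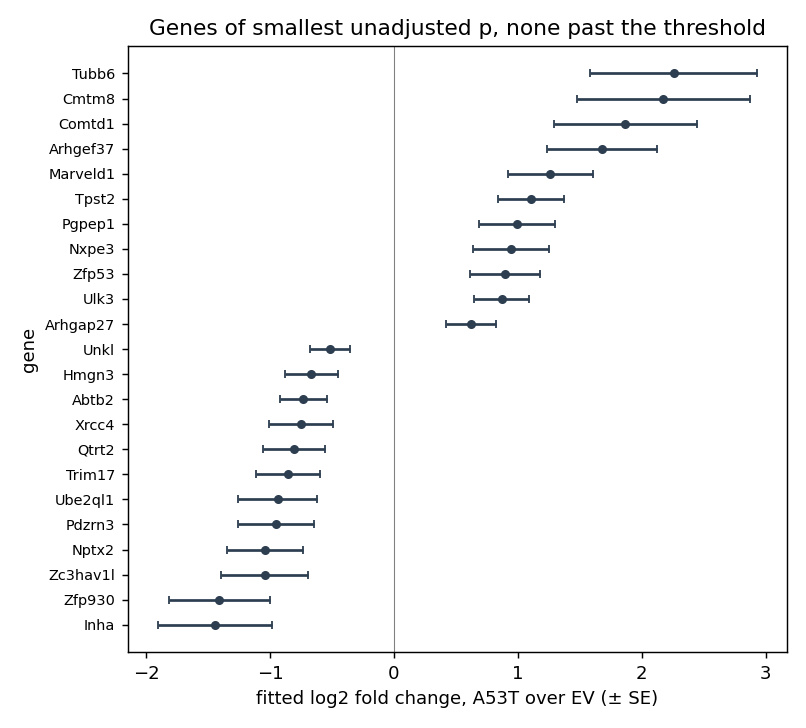
Fitted log2 fold change of A53T over EV with its standard error for the 23 named genes of smallest unadjusted p besides the transgene. None passed the threshold, the adjusted p of each being 0.957.

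Neuronal genes were lower as a group in A53T by the camera test at its preset correlation (adjusted p = 2.92e-04). With an estimated correlation the list was not called (adjusted p = 0.895). The estimated correlation was 0.58 for neurons, 0.88 for striatal projection neurons, 0.80 for astrocytes and 0.68 for oxidative phosphorylation. Each was far above the preset value, so the smaller p-values of these lists rest on an assumption that the libraries did not meet. The direction turned without A53T replicates 3 and 4, left out after seeing the data, with medians of 0.095 for neurons, 0.24 for striatal projection neurons, 0.13 for astrocytes and 0.070 for oxidative phosphorylation. With the covariate for carried-over cells the neuron median was -0.064, and the direction turned for striatal projection neurons (0.031), astrocytes (0.092) and oxidative phosphorylation (0.023). This covariate holds the neuron and astrocyte scores themselves, so it takes out their difference by design and decides nothing about it. All 15 tested neuron genes had a negative fitted fold change, and 0 were called, over all genes or adjusted over the list alone. The median over the members of the difference in mean log2 CPM was -0.68, and medians of the lists below are of this kind. Slc17a7, the vesicular glutamate transporter of cortical neurons, was at 26.5 ± 29.0 CPM in EV and 5.72 ± 5.44 CPM in A53T, and Stmn2 at 24.4 ± 6.24 and 19.7 ± 0.976 CPM (SD, n = 5 each). Slc17a7 had a log2 fold change of -2.21, and of -1.45 without EV replicate 2. Striatal projection neuron genes (12 of 12 lower, median -0.73, adjusted p = 0.00136, and adjusted p = 0.895 with an estimated correlation) included Tac1 (-0.86 ± 0.54, SE) and Gpr6 (-0.43 ± 0.45). Astrocyte genes (12 of 14 lower, median -0.39, adjusted p = 0.0188, and adjusted p = 0.895 with an estimated correlation) included Gjb6 (-0.35 ± 0.28) and Mfge8 (0.23 ± 0.20). Nuclear genes of oxidative phosphorylation (23 of 27 lower, median -0.18, adjusted p = 0.0352, and adjusted p = 0.895 with an estimated correlation) included Cox5a (-0.34 ± 0.26) and Uqcrc2 (0.31 ± 0.24). Without A53T replicate 2 the log2 fold change was -0.81 for Gpr6, -0.64 for Gjb6, 0.087 for Mfge8, -0.58 for Cox5a and 0.093 for Uqcrc2. For Gpr6 it was -0.24 without EV replicate 1, -0.25 without A53T replicate 3 and -0.26 without A53T replicate 4, for Mfge8 it was 0.090 without EV replicate 3, and for Uqcrc2 it was 0.20 without EV replicate 2 and 0.16 without EV replicate 3. Leaving out 1 library moved medians of these lists by over 1.5 times. Without A53T replicate 2 the median was -1.12 for striatal projection neurons, -0.65 for astrocytes and -0.35 for oxidative phosphorylation. Without A53T replicate 3 the median was -0.35 for striatal projection neurons, -0.22 for astrocytes and -0.066 for oxidative phosphorylation. Without A53T replicate 4 the median was -0.35 for neurons, -0.32 for striatal projection neurons, -0.12 for astrocytes and -0.11 for oxidative phosphorylation. Without A53T replicate 5 the median was -0.29 for oxidative phosphorylation. Without EV replicate 1 the median was -0.099 for oxidative phosphorylation. Without EV replicate 3 the median was -0.35 for oxidative phosphorylation.

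Microglial and immune lists were higher in A53T by the same test at its preset correlation, each with an adjusted p of 0.895 with an estimated correlation. The estimated correlation was lowest for disease-associated microglia (0.31) and was 0.95 for homeostatic microglia and for dissociation stress. All of these lists thus lay far above the preset value too. The direction turned for all but disease-associated microglia and border-associated macrophages without A53T replicates 3 and 4, left out after seeing the data. The medians there were -0.29 for homeostatic microglia, -0.14 for MHC class I, -0.32 for MHC class II, -0.16 for complement and Fc receptors, -0.076 for NF-kB and cytokines, -0.19 for dissociation stress and -0.053 for lysosome and autophagy. With the covariate for carried-over cells the direction turned for homeostatic microglia (-0.38), disease-associated microglia (-0.087), MHC class I (-0.044), MHC class II (-0.12), complement and Fc receptors (-0.21), NF-kB and cytokines (-0.24) and dissociation stress (-0.19). It did not turn for border-associated macrophages or for lysosome and autophagy. All 18 homeostatic microglia genes had a positive fold change (median 0.75, adjusted p = 0.00426, and adjusted p = 0.895 with an estimated correlation), such as the transcription factor gene Sall1 (1.08 ± 0.60, SE) and Gpr34 (1.25 ± 0.72). Disease-associated microglia genes, a set induced around protein deposits and dying cells, were higher for 16 of 18 members (median 0.68, adjusted p = 0.0150, and adjusted p = 0.895 with an estimated correlation), with Spp1 at 1.06 ± 1.37 CPM in EV and 7.45 ± 11.3 CPM in A53T and Clec7a at 2.21 ± 2.48 and 10.5 ± 11.5 CPM (SD, n = 5 each). A53T replicate 4 held 593 of the 854 Spp1 reads, and without it the log2 fold change was 1.22 for Spp1 (2.83 with it) and 1.44 for Clec7a (2.23 with it). Complement and Fc receptor genes (15 of 15 higher, median 0.86, adjusted p = 0.00426, and adjusted p = 0.895 with an estimated correlation) included Fcgr2b (1.38 ± 0.67) and Itgam (1.244 ± 0.69). NF-kB and cytokine genes (17 of 17, median 0.77, adjusted p = 0.002, and adjusted p = 0.895 with an estimated correlation) included Casp1 (1.91 ± 0.94) and Il18 (0.41 ± 0.20). Immediate early and dissociation stress genes (19 of 19, median 0.70, adjusted p = 0.00136, and adjusted p = 0.895 with an estimated correlation) included Hspa1b (1.14 ± 0.61) and Rhob (1.01 ± 0.56). The scores of the NF-kB list and of the dissociation stress list followed the homeostatic microglia score over the 10 libraries, with r = 0.986 and 0.989, and 0.987 and 0.990 with group means removed (permutation p = 1.2e-04 and 1.1e-04 for the latter). MHC class I genes (16 of 16, median 0.59, adjusted p = 0.00533, and adjusted p = 0.895 with an estimated correlation) included Psmb9 (1.49 ± 0.64) and H2-Q4 (1.10 ± 0.51), the latter one of several near-identical genes that can share reads. MHC class II genes (13 of 14, median 0.52, adjusted p = 0.0445, and adjusted p = 0.895 with an estimated correlation) included H2-Oa (2.02 ± 1.05) and Cd86 (1.23 ± 0.71). Lysosome and autophagy genes (21 of 26, median 0.38, adjusted p = 0.00285, and adjusted p = 0.895 with an estimated correlation) included Hexa (1.14 ± 0.48) and Atg7 (0.59 ± 0.26). Border-associated macrophage genes (5 of 5, median 1.01, adjusted p = 0.0438, and adjusted p = 0.895 with an estimated correlation) included Siglec1 (2.36 ± 1.08) and Mrc1 (1.47 ± 0.80). The log2 fold change without A53T replicate 4 was 0.78 for Gpr34, 0.66 for Rhob and 0.72 for Hexa, that of Mrc1 was 0.83 without A53T replicate 3, and that of Siglec1 was 3.68 without EV replicate 5. Leaving out 1 library moved medians of these lists by over 1.5 times. Without A53T replicate 2 the median was 1.41 for homeostatic microglia, 1.04 for disease-associated microglia, 0.99 for MHC class I, 1.00 for MHC class II, 1.36 for complement and Fc receptors, 1.38 for NF-kB and cytokines, 1.18 for immediate early and dissociation stress and 0.57 for lysosome and autophagy. Without A53T replicate 3 the median was 0.39 for homeostatic microglia, 0.63 for border-associated macrophages, 0.36 for MHC class I, 0.25 for MHC class II, 0.46 for complement and Fc receptors, 0.40 for immediate early and dissociation stress and 0.19 for lysosome and autophagy. Without A53T replicate 4 the median was 0.35 for homeostatic microglia, 0.29 for disease-associated microglia, 0.26 for MHC class I, 0.22 for MHC class II, 0.39 for complement and Fc receptors, 0.36 for NF-kB and cytokines, 0.36 for immediate early and dissociation stress and 0.20 for lysosome and autophagy. Without A53T replicate 5 the median was 0.84 for MHC class II. Without EV replicate 1 the median was 0.34 for homeostatic microglia, 0.35 for disease-associated microglia, 0.35 for MHC class I, 0.26 for MHC class II, 0.41 for complement and Fc receptors, 0.33 for NF-kB and cytokines, 0.38 for immediate early and dissociation stress and 0.24 for lysosome and autophagy.

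Camera at its preset correlation thus called 13 of 37 lists, 9 higher and 4 lower, with 0 members called by the edgeR test over all genes and 0 adjusted over the list alone. Over these 13 lists the estimated correlation was 0.31 to 0.95, so the calls depend on the preset value. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.895), and fry called 0 (smallest adjusted p = 0.918). The mean scores went from 5.82 ± 1.03 in EV to 6.56 ± 1.77 in A53T for homeostatic microglia (exact permutation p = 0.452) and from 6.59 ± 0.421 to 5.86 ± 1.08 for neurons (exact permutation p = 0.222; SD, n = 5 each). Of 37 list scores 0 reached an unadjusted exact permutation p under 0.05, and 0 passed after adjustment, the smallest adjusted p being 0.881. The number of lists called was 2 without A53T replicate 3, 0 without A53T replicate 4 and 6 without EV replicate 1, and it was 20 without A53T replicate 2 or A53T replicate 5. Among libraries with at least 100 Bpifa2 reads the neuron score differed by -0.34 (3 EV and 2 A53T mice) and among the rest by -0.81 (2 EV and 3 A53T mice), and the homeostatic microglia score by 0.31 and 0.48.

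**Figure D4:**
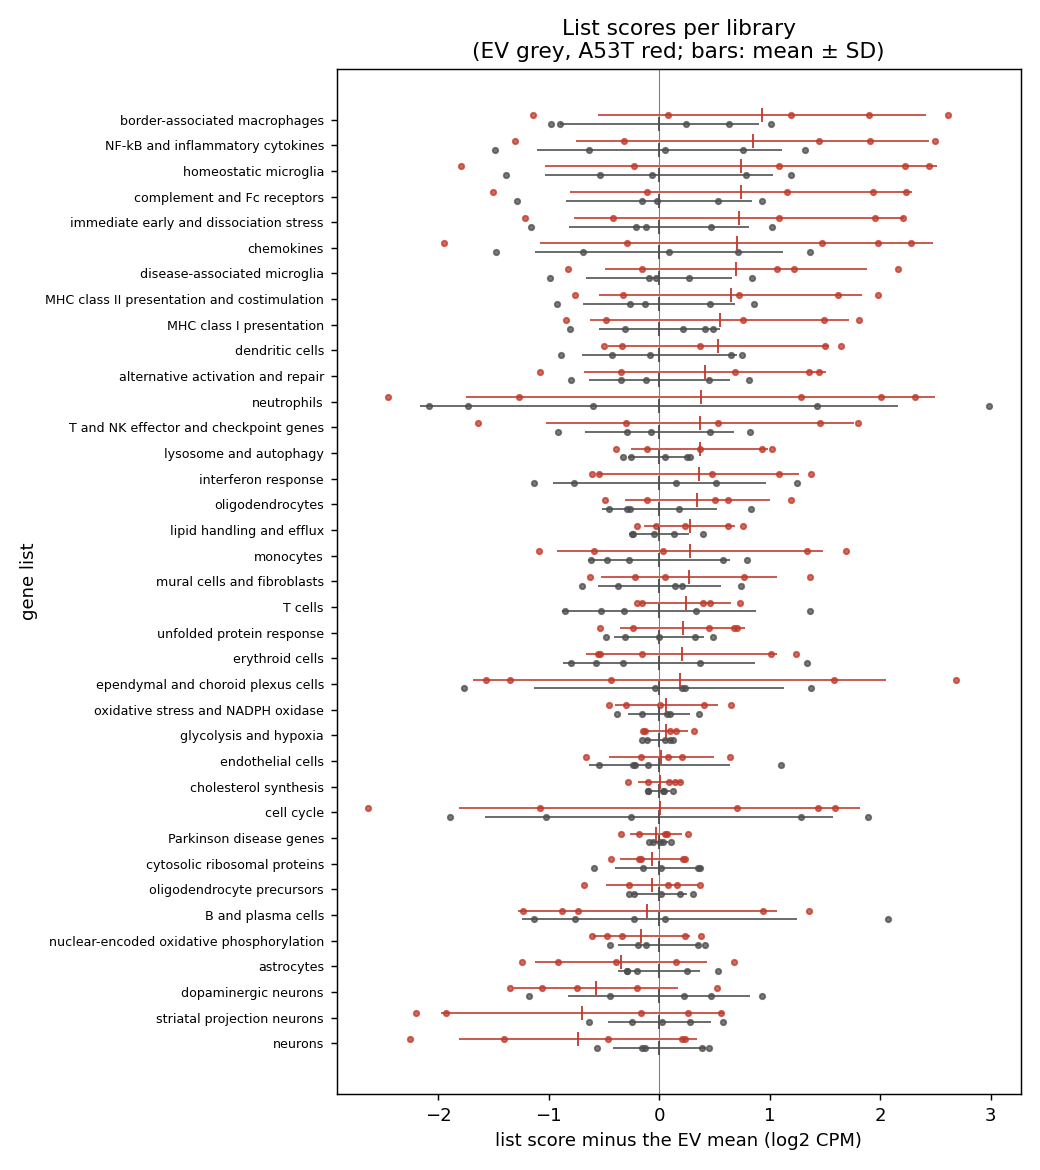
Score of each gene list in each library minus the EV mean of that list (horizontal axis, log2 CPM), for EV (grey) and A53T (red) with mean ± SD, n = 5 each. The A53T range covers most of the EV range in the microglial and neuronal lists, and no list score differed with an exact permutation p under 0.05.

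The other 24 lists did not pass the camera test, and 0 of their members were called over all genes or adjusted over the list alone. They are given with the number of members with a positive fitted fold change, the median difference in mean log2 CPM and the camera adjusted p. The first and second of these can differ in direction, as for neutrophils. Among cell types these were T cells (5 of 11 higher, 0.05, 0.675), B and plasma cells (4 of 12 higher, -0.11, 0.825), neutrophils (1 of 5 higher, 0.50, 0.747), monocytes (5 of 8 higher, -0.12, 0.825), dendritic cells (6 of 8 higher, 0.46, 0.316) and dopaminergic neurons (2 of 10 higher, -0.51, 0.0686). The same values were found for oligodendrocytes (12 of 14 higher, 0.49, 0.0545), oligodendrocyte precursors (5 of 10 higher, -0.12, 0.483), endothelial cells (5 of 14 higher, -0.03, 0.976), mural cells and fibroblasts (11 of 13 higher, 0.29, 0.220), ependymal and choroid plexus cells (3 of 5 higher, 0.11, 0.825) and erythroid cells (4 of 5 higher, 0.26, 0.675). Among programmes they were interferon response (19 of 25 higher, 0.16, 0.117), T and NK effector and checkpoint genes (6 of 9 higher, 0.24, 0.617), chemokines (9 of 11 higher, 0.82, 0.328), alternative activation and repair (7 of 9 higher, 0.33, 0.240), cell cycle (11 of 21 higher, 0.22, 0.825) and cytosolic ribosomal proteins (10 of 37 higher, -0.06, 0.304). The remaining programmes were unfolded protein response (14 of 16 higher, 0.29, 0.164), Parkinson disease genes (7 of 16 higher, -0.04, 0.884), oxidative stress and NADPH oxidase (11 of 18 higher, 0.11, 0.979), cholesterol synthesis (7 of 18 higher, -0.10, 0.743), lipid handling and efflux (9 of 11 higher, 0.29, 0.0686) and glycolysis and hypoxia (7 of 17 higher, -0.06, 0.976). The median, the mean and the direction of the test differed in sign for 5 of these lists, monocytes, endothelial cells, ependymal and choroid plexus cells, cholesterol synthesis and glycolysis and hypoxia. The only higher neutrophil member was Csf3r, with its fewest reads (89) in A53T replicate 2 and its most (4741) in A53T replicate 4. The same held for Lag3 of the T and NK list (33 and 1301) and for microglial P2ry12 (367 and 12292). Neither list can thus be read as a measure of its named cells alone.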

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

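The tests of the transgene, of leaving out A53T replicates 3 and 4, of the microglial to neuronal share and of the shift between microglial programmes were chosen after the results were seen, and the counts over other splits of the mice were planned.

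The edgeR test called 0 genes between the real groups (378 at an unadjusted p under 0.05, with 2 called by DESeq2, 0 by limma-voom and 0 by limma on the rlog values), a count that all 100 of 100 splits of the 10 libraries into groups of 5 must reach, so the splits decide nothing about chance here. The highest of the other splits gave 3552 genes. It set EV replicates 1, 2 and 3 with A53T replicates 2 and 5, the 5 libraries with the lowest microglia minus neuron scores, against the rest, which points to a structure of the samples that is not the vector. The only other split with called genes, 7 of them, set EV replicates 1, 2 and 3 with A53T replicates 1 and 2. Those are the libraries with at least 100 Bpifa2 reads. Whether a shared preparation accounts for either split was not tested.

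Microglial lists were higher and neuronal lists lower in A53T, with 13 lists called at the preset correlation, and 0 called with an estimated correlation (smallest adjusted p = 0.895). Chance cannot be excluded, since 49 of 100 splits gave at least as many called lists and the highest of the others gave 27. Leaving out A53T replicates 3 and 4, the libraries with little neuronal RNA, kept 0 of the 13 calls. It turned the direction of all but disease-associated microglia and border-associated macrophages, with medians going from 0.75 to -0.29 for homeostatic microglia and from -0.68 to 0.095 for neurons. This decides nothing about the cause, since the 2 libraries were picked for having the pattern most strongly. A share of microglial to neuronal RNA that varies between preparations stays open, as the group means of the microglia minus neuron score differed by 1.48 (log2, exact permutation p = 0.325), and its range of 3.53 over single EV mice decides nothing beside a difference of means. A shift from homeostatic to disease-associated microglial genes stays open, with a score difference of -0.05 (exact permutation p = 0.905), and so does an effect of the transgene on the number of microglia recovered, which was not tested. In A53T replicates 1 to 5 the homeostatic microglia scores were 6.91, 4.02, 8.04, 8.26 and 5.59, beside 1520, 2223, 10, 1397 and 1217 transgene reads. The score did not rise with the reads, but 5 libraries whose neuronal RNA also varied cannot decide this.

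A53T replicate 3 held 10 transgene reads where the other A53T libraries held 1217 to 2223. A swap with an EV library is argued against by the highest transgene count in an EV library, which was 1 read. A library from an EV mouse under a wrong label stays open, though the exact binomial p for 10 reads at the pooled EV rate was 1.35e-06. That p takes reads as independent, and without molecular identifiers PCR copies of fewer molecules cannot be told apart. The rate also rests on a single read, and cross-over between libraries can differ from one to the next. Little neuronal RNA is argued against by 0.504 transgene reads per 1000 reads of the neuron list, against at least 21.99 in the other A53T libraries. A missed or weak injection may account for it and was not tested, since no other measure of the injection is among the values used here.

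Chance flags about 1 group in 20, and 77 measures were examined in each group. Of the 154 group tests 8 were flagged, about as many as chance alone would give. The values that stood apart from the others of their group are given as values. EV replicate 3 had an endothelial list score of 5.67 against at most 4.46 in the other EV libraries, a second principal component of -124.7 against 13.3 to 24.5, and 5.31 CPM of Ly6c2 against at most 1.72. EV replicate 2 had the single transgene read of that group, 0.0613 CPM. EV replicate 1 had 3.18 CPM of Zfp53 against at least 6.02, and EV replicate 4 had 0.985 CPM of Cd8a against at most 0.238. A53T replicate 4 had 15.4 CPM of Cmtm8 against at most 4.83 and 2.73 CPM of Ly6c2 against at most 0.638.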

How the results depend on the processing

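Of these alternatives, leaving out A53T replicates 3 and 4, the microglia minus neuron covariate, the removal of ribosomal RNA rows and the gland transcript term were chosen after seeing the data. edgeR called 0 genes in the main comparison (378 at an unadjusted p under 0.05). The count was 1 with the replicate block, 1 leaving out A53T replicates 3 and 4, and 2 with DESeq2, and leaving out each library in turn gave 0 to 1. It was 0 under the other edgeR and limma alternatives. The single gene in each edgeR fit was the transgene, whose log2 fold change was 12.01 with the replicate block (edgeR adjusted p = 2.40e-04), 12.35 leaving out A53T replicates 3 and 4 (adjusted p = 6.66e-07) and 12.09 with DESeq2 (adjusted p = 1.39e-10), and 11.48 to 13.36 leaving out each library in turn. The replicate numbers do not pair the mice, since same-numbered libraries deviated from their group means with r from -0.37 to 0.31 and no library matched its own number best. The block moved the number of lists called from 13 to 15.

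The number of lists called was 2 with the covariate for carried-over cells, 4 leaving out A53T replicates 3 and 4, 1 with the microglia minus neuron covariate, 8 with the gland transcript term, 0 with an estimated correlation, 0 with fry, and 0 to 20 leaving out each library in turn. Of the 13 lists called, 0 were kept with the first 3 of these alternatives, 8 with the gland transcript term, 13 with DESeq2-style size factors and 11 with the stricter filter. The covariates among the first 3 are built from scores of the tested lists, so losing the calls there is not independent evidence. Fewer libraries entered the fits that leave some out. For the other alternatives the cause was not tested. The list scores gave 0 differences in the main test and in each alternative run. The smallest p of the exact permutation test on 10 libraries is 0.00794, at which no list could pass on its own after adjustment over 37 lists. Several lists at that p could have passed together, so the count of 0 was not fixed in advance. In the main test the smallest unadjusted p of the exact permutation test was 0.222, and no list came near the limit. With 10 libraries a count of 0 still says little about stability. The 23 genes of smallest p besides the transgene kept their sign in all 575 pairs of a gene and an alternative, and none passed the threshold in any. They were picked for a small p in these same libraries, which the alternatives fit again. A kept sign was thus close to fixed in advance and says little about these genes. Over the 58 named genes reported here, 47 of 1446 pairs had the other sign, and over the 37 lists 137 of 777 pairs had the other direction in the list test. The transgene had no value with the stricter filter or without ribosomal RNA rows, since the 10 reads of A53T replicate 3 took it under the filter. Cd3e and Cd8a stayed untested, with 82 and 83 reads in all, and whether depth or few T cells accounts for this was not tested.

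The pairs that changed direction follow, as log2 fold changes of genes and median log2 differences of lists, and the direction of a list is that of its test, which can differ from its median. The cause was not tested. With the replicate block, these genes were Cd4 -0.21, S100a8 0.56 and Cldn5 -0.053. With the replicate block, the lists were oxidative stress and NADPH oxidase 0.11 and glycolysis and hypoxia -0.055. With DESeq2-style size factors, this gene was Cldn5 -0.041. With no filter, the lists were neutrophils 0.16, endothelial cells -0.021, cell cycle 0.22 and oxidative stress and NADPH oxidase 0.11. With the stricter filter, the lists were T cells -0.20, B and plasma cells -0.046 and glycolysis and hypoxia -0.055. With the covariate for carried-over cells, these genes were P2ry12 -0.40, Tmem119 -0.19, Snap25 0.015, Mbp 0.15, Cldn5 -0.28, Gpr34 -0.17, Gpr6 0.026, Itgam -0.027 and Rhob -0.016. With the covariate for carried-over cells, the lists were homeostatic microglia -0.38, neutrophils -0.84, monocytes -0.29, dendritic cells -0.11, striatal projection neurons 0.031, astrocytes 0.092, oligodendrocyte precursors 0.10, endothelial cells -0.11, mural cells and fibroblasts -0.023, erythroid cells -0.016, disease-associated microglia -0.087 and MHC class I presentation -0.044. Further lists there were MHC class II presentation and costimulation -0.12, T and NK effector and checkpoint genes -0.24, complement and Fc receptors -0.21, NF-kB and inflammatory cytokines -0.24, chemokines -0.43, alternative activation and repair -0.13, immediate early and dissociation stress -0.19, cell cycle -0.80, nuclear-encoded oxidative phosphorylation 0.023, unfolded protein response -0.15, Parkinson disease genes 0.11 and oxidative stress and NADPH oxidase -0.016. Further lists there were cholesterol synthesis 0.035 and glycolysis and hypoxia -0.0060. Leaving out A53T replicates 3 and 4, these genes were P2ry12 -0.31, Snap25 0.085, Mbp 0.28, Aqp4 0.051, Cldn5 -0.42 and Rhob -0.025. Leaving out A53T replicates 3 and 4, the lists were homeostatic microglia -0.29, neutrophils -0.89, monocytes -0.34, dendritic cells -0.19, neurons 0.095, striatal projection neurons 0.24, astrocytes 0.13, oligodendrocytes -0.037, oligodendrocyte precursors 0.13, endothelial cells -0.23, mural cells and fibroblasts -0.22 and erythroid cells 0.064. Further lists there were MHC class I presentation -0.14, MHC class II presentation and costimulation -0.32, T and NK effector and checkpoint genes -0.70, complement and Fc receptors -0.16, NF-kB and inflammatory cytokines -0.076, chemokines -0.25, alternative activation and repair -0.15, immediate early and dissociation stress -0.19, cell cycle -0.81, nuclear-encoded oxidative phosphorylation 0.070, cytosolic ribosomal proteins 0.10 and unfolded protein response -0.16. Further lists there were lysosome and autophagy -0.053, Parkinson disease genes 0.15, oxidative stress and NADPH oxidase 0.0081, lipid handling and efflux -0.028 and glycolysis and hypoxia -0.017. With the microglia minus neuron covariate, these genes were P2ry12 -0.39, Tmem119 -0.089, Mbp 0.064, Cldn5 -0.29, Fcgr2b -0.089 and Hspa1b -0.036. With the microglia minus neuron covariate, the lists were homeostatic microglia -0.21, neutrophils -0.62, monocytes -0.36, dendritic cells -0.048, astrocytes 0.028, oligodendrocyte precursors 0.066, endothelial cells -0.16, mural cells and fibroblasts 0.0041, erythroid cells 0.054, interferon response -0.048, MHC class I presentation 0.026 and MHC class II presentation and costimulation -0.063. Further lists there were T and NK effector and checkpoint genes -0.44, complement and Fc receptors -0.060, NF-kB and inflammatory cytokines -0.085, chemokines -0.22, alternative activation and repair -0.023, immediate early and dissociation stress -0.080, cell cycle -0.92, nuclear-encoded oxidative phosphorylation 0.047, cytosolic ribosomal proteins 0.068, unfolded protein response -0.10, Parkinson disease genes 0.072 and oxidative stress and NADPH oxidase 0.022. Further lists there were cholesterol synthesis 0.017 and glycolysis and hypoxia 0.064. With the gland transcript term, this gene was Cldn5 -0.045. With the gland transcript term, the lists were cell cycle -0.15, Parkinson disease genes -0.013, oxidative stress and NADPH oxidase 0.012 and glycolysis and hypoxia 0.025. With DESeq2, this gene was Cldn5 -0.041. With limma-voom, these genes were S100a8 0.019 and Mfge8 -0.016. With limma on the rlog values, these genes were Cd4 -0.13 and Cldn5 -0.059. With the surrogate variable, these genes were P2ry12 -0.31, Tmem119 -0.027, Mbp 0.054, Cldn5 -0.30 and Fcgr2b -0.028. With fry, the lists were glycolysis and hypoxia -0.055.

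Leaving out each library in turn moved Cldn5 -0.19 to 0.10, monocytes -0.34 to 0.18, endothelial cells -0.17 to 0.27, cell cycle -0.48 to 0.60, glycolysis and hypoxia -0.13 to 0.091, S100a8 -1.09 to 0.84, cytosolic ribosomal proteins -0.24 to 0.016, B and plasma cells -0.47 to 0.34 and neutrophils -0.39 to 1.04. It also moved oxidative stress and NADPH oxidase -0.066 to 0.17, erythroid cells 0.019 to 0.53, Cd4 -0.27 to 0.33, ependymal and choroid plexus cells -0.80 to 0.31, cholesterol synthesis -0.19 to 0.014, T and NK effector and checkpoint genes -0.24 to 0.55, Parkinson disease genes -0.14 to 0.0046, Mbp -0.46 to 0.068, oligodendrocyte precursors -0.29 to 0.037 and mural cells and fibroblasts -0.028 to 0.45.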

Other observations

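Each of the tests in these paragraphs was chosen after the results were seen. The unnamed gene B430306N03Rik, on chromosome 17 (48315279 to 48326511, GRCm38.p6), had 41, 25, 30, 96 and 9 reads in A53T replicates 1 to 5 and 0, 0, 0, 2 and 2 in the EV replicates. That is 2.04 ± 1.46 CPM in A53T and 0.0399 ± 0.0547 CPM in EV (SD, n = 5 each; exact permutation p = 0.00794, the smallest possible). It was singled out after its values were seen, as a gene called by DESeq2 (adjusted p = 0.00156). The default filter of edgeR had removed it, and with no filter its edgeR log2 fold change was 5.33 ± 1.11 (SE) with an adjusted p of 0.513.

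Transcripts of salivary gland were present in libraries of both groups, at levels that differed between libraries. Bpifa2, a secreted salivary protein gene, had 972, 1727 and 1767 reads in EV replicates 1, 2 and 3 and 477 and 2114 in A53T replicates 1 and 2, and at most 37 in the other 5 libraries. Smr3a came to 32.5% to 46.9% of the Bpifa2 reads in those 5 libraries and Car6 to 22.01% to 40.7%. Ttr, the choroid plexus transthyretin gene, had 8067 reads in A53T replicate 4, 1972 in A53T replicate 3 and 1261 in EV replicate 5, and at most 110 in the others.

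The cell cycle score minus the homeostatic microglia score was -4.26 ± 0.705 in EV and -5.00 ± 0.202 in A53T (SD, n = 5 each), a difference that did not pass its test. The cell cycle list itself had 11 of 21 members higher (camera adjusted p = 0.825). A lower level of dividing microglia is a hypothesis that the exact permutation p of 0.0873 leaves open. Over the leave-one-out sets the difference was -0.98 to -0.57, and the exact permutation p was 0.0159 without EV replicate 2 and 0.0794 to 0.127 otherwise. With the microglia minus neuron score as a covariate, 20 of 21 cell cycle genes were lower (camera adjusted p = 7.54e-08, and 0.952 with an estimated correlation), with 0 called by edgeR over all genes and 3 adjusted over the list alone. Camera also called the list lower with the covariate for carried-over cells (median -0.80, adjusted p = 1.43e-05, and 0.972 with an estimated correlation) and without A53T replicates 3 and 4 (-0.81, adjusted p = 0.00905, and 0.975). Without A53T replicate 2 it called the list higher (0.55, adjusted p = 0.0458, and 0.693 with an estimated correlation). Dropout of scarce transcripts cannot be told apart from a lower level of dividing microglia with 10 libraries. With group means removed, the score had r = 0.34 to the microglial score (permutation p = 0.22). The score holds the microglial score with a minus sign, which lowers this r by construction, so it decides nothing about dropout. The difference among the 3 libraries of each group with the most microglial RNA was -0.75, which goes against dropout with too few libraries for a decision. Dividing blood cells cannot be told apart either, with r = 0.13 to the B and plasma cell score (permutation p = 0.808, group means removed).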
